A study of Mus musculus with 8 samples.

How the data were processed

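The study profiled lumbar 4 and 5 dorsal root ganglia of C57BL/6 mice 3 days after sham surgery or sciatic nerve axotomy (SNI in the sample names), in mice with floxed Myh9 and Myh10 (WT) and in mice that also carried Advillin-Cre (dKO). Per the labels' protocols, total RNA was isolated with a column kit and made into paired-end libraries with a TruSeq RNA kit. The labels do not say whether the kit kept strand, so reads of overlapping and antisense genes cannot be told apart. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0 and edgeR (no version) and the builds GRCm38.p4 and mm10, with no role or order. HISAT2 is an aligner and StringTie an assembler and quantifier of transcripts; which annotation was used, how reads that fit several places were assigned and whether any scaling followed are not given in the sources used here.

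The authors deposited 1 table of FPKM values, that is fragment counts scaled to transcript length and to the library's mapped fragments, with 21878 gene symbols and 8 columns. Each column was matched to its sample by the column name given in that sample's description, and all 8 columns were matched. FPKM divides by a library's total, so a group of very abundant transcripts lowers all others, and by transcript length, so it depends on the transcript models. The table names genes by symbol only; 27 symbols look like dates made by a spreadsheet and 2 symbols are duplicated, and these are not interpreted. Gapdh is listed at 3.29 to 6.56 FPKM while Actb is at 328 to 558 FPKM, and Ppia and Eef1a1, which also have processed copies, reached 1403 to 3893 and 769 to 1483 FPKM. The cause of the low Gapdh value was not tested. Mitochondrially encoded genes were not analysed here. Totals of FPKM per library were 278310 to 339920, and 11696 to 12478 genes reached 1 FPKM. The 10 most abundant genes held 5.55 to 9.01% of the total.

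Read totals are unknown, and relative depth was not recovered. Of 2726 ratios of low values, 51.3% lay within 0.1 of a whole number, where 20% would by chance, so whole reads were not recovered and no count model was run.

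The analysis started from the deposited FPKM. Genes with at least 1 FPKM in at least 2 of the 8 libraries were kept (12884) and log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3. The model had 1 mean per group over all 8 libraries (4 residual degrees of freedom), so the 4 groups share the estimate of spread, with empirical Bayes moderation and a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. The contrasts were WT SNI vs WT sham, dKO SNI vs dKO sham, dKO sham vs WT sham, dKO SNI vs WT SNI, and the difference of the 2 injury contrasts (interaction). A further model had additive terms for genotype and surgery. Replicate libraries correlated at a Pearson r of 0.984 to 0.989 over genes and no 2 libraries were identical. A gene's groups of 2 libraries fall apart by chance in 33.3% of genes; they did so in 46.1 to 75.5% of genes. A permutation test of 2 against 2 libraries cannot go below p = 0.333, so single genes were not tested that way.

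Before the data were examined, 32 gene lists were fixed for the tissue and the injury (regeneration, neuronal function, stress, metabolism, immune cells, and markers of the other cell types a ganglion or its surroundings could hold); 769 of their 793 entries were found in the table, and 31 lists had at least 3 tested members. Lists were tested with camera at its preset correlation of 0.01, adjusted over the lists, and as alternatives with an estimated correlation and with fry, which asks whether a list's genes move 1 way without comparing them with other genes. With the estimated correlation no list passed in any comparison. Its lowest adjusted p in a comparison was 0.365 to 0.441, and 0.365 for the macrophage markers in WT SNI vs WT sham, with 26 of 26 called. A list that does not pass it is therefore not shown to be unchanged. The estimated correlations, such as 0.274 (macrophage), 0.797 (ribosomal) and 0.964 (muscle), exceeded the preset 0.01, so the preset p can be too small. Fry called 13 lists in WT SNI vs WT sham, 21 in dKO SNI vs dKO sham and 15 in dKO SNI vs WT SNI. It called 0 in dKO sham vs WT sham and in the interaction. The fixed rule for named genes took the targeted genes and Avil in every library, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, and the members of each list with the smallest p (3, or 4 for called lists and the regeneration-associated genes). Predicted genes count but need not be named. Counts of genes named by the fixed rule took 3 members for called lists as well, except the regeneration-associated genes. Genes outside that rule, chosen after their values were seen, were Eif2s3x, Ckm and Acta1 per library, Hbb-bs, Bdnf and Jun in dKO SNI vs dKO sham, Atf3, Gpr151, Stmn4, Nppb and Kif22 in dKO SNI vs WT SNI, Eif2s3y and Ddx3y in the averaged injury response, and Gm38495. Eln and Mfap4 in the injured groups and Ctsg and Ms4a3 in dKO SNI vs WT SNI were chosen in the same way.

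The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median centring, quantile normalization, fitting the 4 compared libraries only, no trend, robust moderation, library quality weights, the replicate number as a block, a minimum log2 change of 1, and leaving out each library in turn. Added after seeing the data were the genes on X and Y left out, the muscle list left out, a term for Y-linked transcripts, and SNI vs sham averaged over genotypes, in which each surgery holds 1 group with and 1 group without those transcripts. The gene tests were tested on simulated data with 200 changed genes among the 12884. For WT SNI vs WT sham it recovered 6.15% of genes changed by 0.5, 64.7% of those changed by 1 and 100% of those changed by 2 on the log2 scale, with 4 false calls. For dKO SNI vs WT SNI there were 9 false calls. The simulated noise was independent between genes and libraries, so deviations that many genes of a library share are not covered. Coordinates came from the GENCODE M21 annotation of GRCm38. Chromosomes came from RefSeq gene records, matched by symbol for 96.1% of tested genes.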

Results

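Gene expression was measured by paired-end RNA sequencing in lumbar 4 and 5 dorsal root ganglia of C57BL/6 mice, 3 days after sham surgery or after cutting of the sciatic nerve, whose sensory axons arise in these ganglia. The ganglia hold the cell bodies of sensory neurons, the satellite glia around them, Schwann cells, fibroblasts, vessels and resident macrophages. WT mice carried loxP-flanked alleles of Myh9 and Myh10, which encode the heavy chains of non-muscle myosin IIA and IIB, and no Cre. dKO mice carried the same alleles with Cre expressed from Advillin (Avil), a gene active in sensory neurons. The sample names call the axotomy SNI, and that name is kept here. The 4 groups (WT sham, WT SNI, dKO sham and dKO SNI) held 2 libraries each, 8 in all. The values were FPKM, and their totals per library ran from 278310 in WT sham 2 to 339920 in dKO SNI 2. Read totals were not given, so the counting error behind a value is unknown. Nothing in the sample descriptions states that the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. All changes are differences of log2(FPKM + 1), a scale that understates the change of genes with low values, and ± after such a change is its standard error in limma.

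The targeted genes were read in every library first. Myh9 measured 27.2 and 31.6 FPKM in the WT sham libraries and 10.9 and 12.1 FPKM in the dKO sham libraries, but 24.6 and 24.4 FPKM in dKO SNI against 30.8 and 29.7 FPKM in WT SNI. Myh10 measured 18.1 and 23.5 FPKM in WT sham, 12.2 and 14.4 FPKM in dKO sham, 13.8 and 10.4 FPKM in WT SNI, and 5.31 and 4.12 FPKM in dKO SNI. Avil, the gene whose promoter drives Cre, measured 172 and 180 FPKM in WT sham, 143 and 112 FPKM in WT SNI, 75.3 and 80.0 FPKM in dKO sham, and 44.1 and 34.5 FPKM in dKO SNI. Every dKO library lay below every WT library of the same surgery for all 3 genes. The values cover whole genes, so they do not isolate the exons that Cre removes, and cells without Avil keep their Myh9 and Myh10. In the mouse assembly GRCm38, Myh9 lies on the minus strand of chromosome 15 (77760587 to 77842175), Myh10 on the plus strand of chromosome 11 (68691559 to 68816632) and Avil on the plus strand of chromosome 10 (127000709 to 127020994), all 3 annotated as protein-coding.

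**Figure D1:**
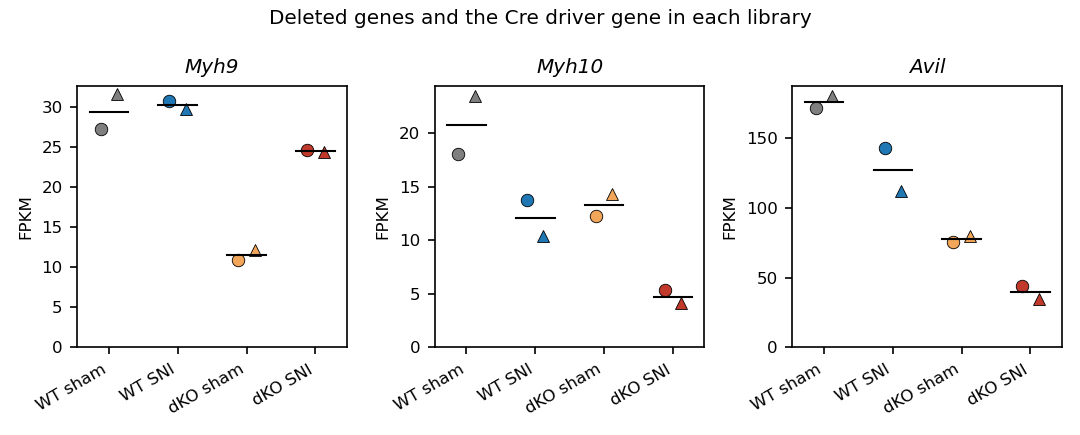
FPKM of Myh9, Myh10 and Avil (vertical axes, each from 0) in the 8 libraries, by group; circles are replicate 1, triangles replicate 2, and bars the mean of 2 libraries. Myh9 lies at 10.9 and 12.1 FPKM in dKO sham and at 24.4 to 31.6 FPKM in the other 6 libraries, while Myh10 is lowest in dKO SNI.

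The Y-linked genes divided the groups in another way. Ddx3y, Eif2s3y, Kdm5d and Uty measured between 2.10 and 17.8 FPKM in the 4 libraries of WT sham and dKO SNI, and between 0 and 0.0109 FPKM in the 4 libraries of WT SNI and dKO sham. WT SNI and WT sham, dKO SNI and dKO sham, and the groups of each genotype comparison therefore differed in Y-linked transcripts as well as in the named factor. The X-linked gene Eif2s3x measured 16.5 and 15.5 FPKM in WT sham, 12.7 and 12.5 FPKM in dKO SNI, 28.3 and 22.3 FPKM in dKO sham, and 16.4 and 30.3 FPKM in WT SNI. WT sham 2 also stood apart in skeletal muscle transcripts. Ckm, muscle creatine kinase, measured 138 FPKM there and at most 3.17 FPKM in the other 7 libraries, and Acta1, skeletal muscle actin, measured 149 FPKM against at most 3.01 FPKM. Hemoglobin transcripts made up 0.473 and 0.461% of all FPKM in WT sham, 0.648 and 1.62% in WT SNI, 0.712 and 1.69% in dKO sham, and 2.29 and 0.906% in dKO SNI.

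**Figure D2:**
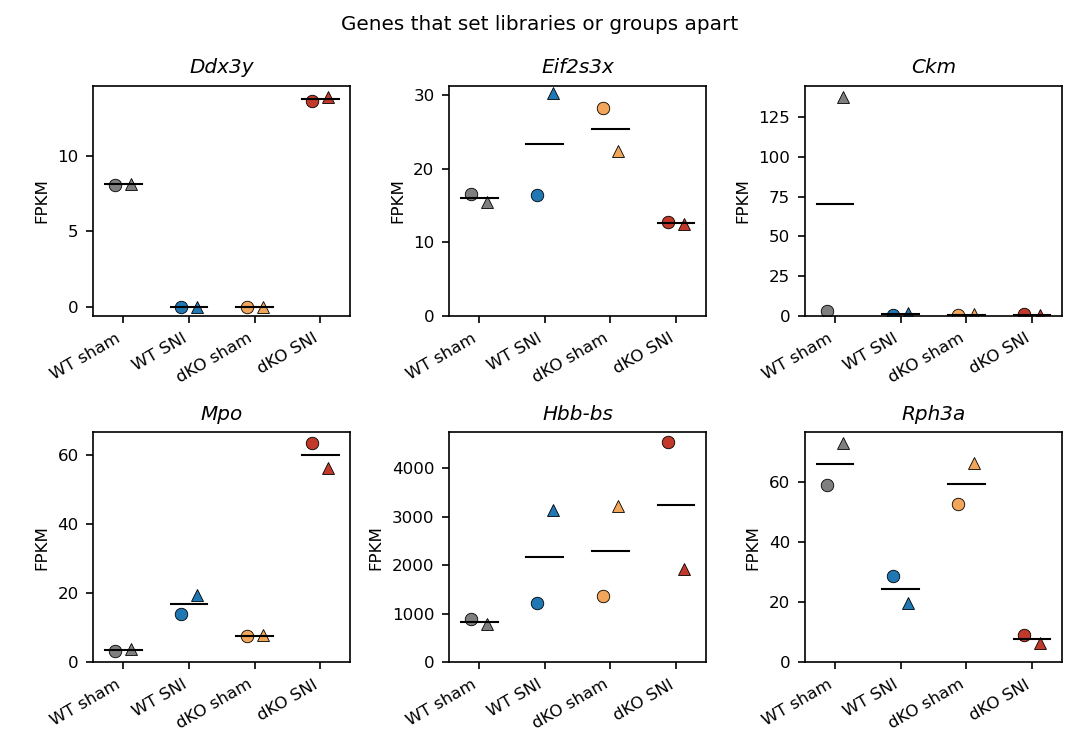
FPKM (vertical axes, from about 0) of Ddx3y, Eif2s3x, Ckm, Mpo, Hbb-bs and Rph3a in the 8 libraries, by group; circles are replicate 1, triangles replicate 2, and bars the mean of 2 libraries. Ddx3y is at or near 0 in WT SNI and dKO sham, Ckm is high in WT sham 2 alone, Mpo is highest in both dKO SNI libraries, and Hbb-bs differs between the 2 libraries of dKO SNI (4547 and 1921 FPKM).

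The first comparison asked what axotomy does in ganglia with both myosin genes intact. Genes of the neuronal injury response rose most in WT SNI. Sprr1a, a small proline-rich protein induced in injured sensory neurons, rose from 12.6 ± 13.2 to 909 ± 234 FPKM (SD, n = 2). The transcription factor Atf3 rose from 4.99 ± 3.22 to 162 ± 22.1 FPKM. The neuropeptides Npy (log2 change 5.08 ± 0.38), Gal (4.58 ± 0.39) and Nts (4.64 ± 0.23) rose as well. The receptor Gpr151 (4.98 ± 0.31), the endopeptidase Ecel1 (3.89 ± 0.24), the gastrin receptor Cckbr (3.77 ± 0.17), the neuropeptide Ucn (3.91 ± 0.49) and Wfdc3 (4.20 ± 0.21) completed the 10 largest rises. Among the largest falls beside the Y-linked genes were the matrix protein Comp (-2.07 ± 0.19), the somatostatin receptor Sstr2 (-1.87 ± 0.14), the itch receptor Mrgprx1 (-1.84 ± 0.34), whose close paralogs can share its reads, and Igsf21 (-1.62 ± 0.19). The ceramide synthase Cers1 (-1.63 ± 0.36) and the potassium channel subunit Kcnf1 (-1.94 ± 0.45) were among them too. Of 38 measured regeneration-associated genes, 32 rose, none fell, and the median change was 2.51, with Stmn4 at 3.28 ± 0.13 and Fgf3 at 3.34 ± 0.16. Of 27 transcription factors linked to regeneration, 15 rose and 1 fell, with Sox11 at 2.81 ± 0.19 and Klf6 at 1.40 ± 0.12. Adjusted over the list alone, 34 of the regeneration-associated genes and 17 of the transcription factors rose. The camera test placed both lists above other genes, at adjusted p 5.1e-23 and 3.31e-05. With an estimated correlation the adjusted p was 0.365 and 0.382.

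Genes that define resting sensory neurons fell in WT SNI. Of 41 ion channels and receptors, 28 fell and 2 rose (33 fell and 2 rose adjusted over the list alone). Among them the sodium channel Scn10a fell from 130 ± 5.32 to 46.1 ± 2.04 FPKM, Scn1a changed by -1.20 ± 0.14 and the mechanosensitive channel Piezo2 by -1.03 ± 0.12. Of 30 markers of neuronal subtypes, 16 fell and 2 rose (21 and 2 adjusted over the list alone), with Lpar5 at -1.12 ± 0.13, the peptide precursor Tac1 at -1.27 ± 0.17 and Gfra2 at -1.29 ± 0.19. Of 27 synaptic vesicle genes, 14 fell and 1 rose (16 and 1 adjusted over the list alone), with the complexin Cplx2 at -1.06 ± 0.20. These 3 lists lay below other genes by camera (adjusted p 3.56e-14, 9.87e-09 and 1.63e-07), but their adjusted p was 0.408, 0.408 and 0.465 with an estimated correlation. Of 20 pan-neuronal markers 5 fell and 1 rose (7 and 2 adjusted over the list alone), with a camera adjusted p of 0.0293 and 0.563 with an estimated correlation, and the call was lost without WT SNI 2 (0.143), without WT sham 2 (0.0534) and with a mean of at least 5 FPKM (0.0558).

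Transcripts of immune and dividing cells rose in the same libraries. Of 15 neutrophil markers 8 rose (10 adjusted over the list alone, median 1.08), with a camera adjusted p of 2.02e-05 and 0.503 with an estimated correlation. Of 10 erythrocyte markers 3 rose, the same adjusted over the list alone (camera adjusted p 0.00536, and 0.563 with an estimated correlation), and the call was lost without WT SNI 2 (0.0618). Of 52 cytosolic ribosomal protein genes 12 rose (32 adjusted over the list alone, median 0.58), with a camera adjusted p of 6.72e-08 and 0.559 with an estimated correlation. Without WT SNI 2 the neutrophil median was 0.63 and the ribosomal median 0.38. All 26 macrophage markers rose, also adjusted over the list alone (median 1.67), with the mannose receptor Mrc1 going from 1.89 ± 0.17 to 20.5 ± 2.14 FPKM and Cd68 at 2.62 ± 0.18. Of 22 complement and antigen presentation genes 15 rose (17 adjusted over the list alone), led by the complement genes C1qa (2.94 ± 0.25), C1qb (2.95 ± 0.18) and C1qc (2.95 ± 0.24). Of 34 cell cycle genes 28 rose (31 adjusted over the list alone), with the spindle protein Prc1 at 2.72 ± 0.15. Of 23 cytokines and chemokines 12 rose (14 adjusted over the list alone), with the macrophage growth factor Csf1 at 2.55 ± 0.19 and Ccl9 at 2.10 ± 0.18. The interleukin gene Il24 was listed at 0 in both WT sham libraries and measured 2.46 ± 0.54 FPKM (SD) in WT SNI. Of 24 fibroblast and matrix genes 18 rose (20 adjusted over the list alone), with the collagens Col3a1 at 2.30 ± 0.18 and Col1a1 at 2.09 ± 0.22. Of 28 genes of the endoplasmic reticulum and integrated stress responses 16 rose (21 adjusted over the list alone), with Chac1 at 1.91 ± 0.19. Camera gave the last 6 lists adjusted p between 8.37e-18 and 3.58e-06, and with an estimated correlation between 0.365 and 0.423.

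The 10 skeletal muscle markers were lower as a list in WT SNI (median -2.58, camera adjusted p 5.88e-04, and 0.559 with an estimated correlation), with no member called over all genes or adjusted over the list alone. The call was lost without WT sham 2 (0.0534), where the median was -0.58, and the median was -4.77 without WT sham 1. In total 2967 of 12884 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg) in WT SNI against WT sham, 1758 higher and 1209 lower. The share of higher genes was 59.3% and became 49.3% after centring the libraries on their median and 45.9% after quantile normalization. Leaving out a library moved the count, to 1101 without WT sham 2 (the library with muscle transcripts), 1133 without WT SNI 2 and 1389 without WT sham 1. Cers1 and Myh10 (-0.74 ± 0.18) lost their calls without WT sham 2 (adjusted p 0.0813 and 0.161) and without WT SNI 2 (0.0858 and 0.148), and Kcnf1 without any 1 of the 4 libraries compared (0.0526 to 0.0696). Without the filter on low values these 3 genes stood at 0.0504 to 0.0599, and Kcnf1 stood at 0.0521 with robust moderation.

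The same comparison in dKO mice asked what axotomy does in mice whose sensory neurons carry Cre and the floxed alleles. The neuropeptide Nts (log2 change 4.25 ± 0.23), Gpr151 (4.17 ± 0.31), Sprr1a (4.07 ± 0.66), Atf3 (3.89 ± 0.30), Gal (3.72 ± 0.39), Npy (3.52 ± 0.38), Wfdc3 (3.97 ± 0.21) and the lipase Lipn (3.49 ± 0.15) rose most beside the Y-linked Eif2s3y (4.18 ± 0.12) and Ddx3y (3.88 ± 0.12). The serotonin receptor channel Htr3a fell most, from 72.6 ± 7.33 to 7.90 ± 3.42 FPKM. The other large falls were of the pentraxin Nptx1 (-2.84 ± 0.25), the vesicle protein Rph3a (-2.82 ± 0.22), the nociceptor receptor Mrgprd (-2.73 ± 0.26), Lgi3 (-2.73 ± 0.30) and the transcription factor Pou4f3 (-2.66 ± 0.21), followed by Mrgprx1 (-2.58 ± 0.34), Tpbgl (-2.43 ± 0.25), Susd2 (-2.41 ± 0.22) and Tmem255a (-2.39 ± 0.27). Of the 38 regeneration-associated genes 31 rose and 1, Bdnf, fell (32 and 1 adjusted over the list alone), at a median of 2.06. Jun, which rose in WT (0.98), measured 40.5 ± 4.00 FPKM in dKO sham and 45.9 ± 3.88 FPKM in dKO SNI and did not pass the threshold. The difference between the 2 Jun responses (-0.80 ± 0.31, adjusted p 0.303) did not pass it either. Camera placed the regeneration-associated genes above other genes at adjusted p 1.11e-13, and at 0.392 with an estimated correlation.

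Of the 41 ion channels and receptors 35 fell and 1 rose. Of the 30 subtype markers 24 fell and none rose, and of the 27 synaptic vesicle genes 24 fell and 1 rose. Adjusted over the list alone the 3 counts were the same, and the medians were -1.34, -1.13 and -1.42. Scn1a fell by 1.84 and Cplx2 by 2.14 on the log2 scale. All 26 macrophage markers rose (median 2.31), and so did all 15 neutrophil markers (median 2.67). Mpo, myeloperoxidase of neutrophil granules, went from 7.64 ± 0.18 to 59.9 ± 5.09 FPKM and Elane, neutrophil elastase, from 8.03 ± 2.58 to 82.7 ± 6.15 FPKM. Of 32 interferon response genes 24 rose (26 adjusted over the list alone), with Psmb9 at 2.06 ± 0.22 and Oas2 at 1.80 ± 0.20. In WT 2 of them rose and 1 fell (1 and 1 adjusted over the list alone), and the camera test of the difference between the responses had an adjusted p of 3.53e-13, or 0.436 with an estimated correlation. Of 52 cytosolic ribosomal protein genes 49 rose (median 1.18), and of 34 cell cycle genes 33 rose (median 1.27). For these macrophage, neutrophil, ribosomal and cell cycle lists the counts adjusted over the list alone were the same. The 8 lists passed camera (adjusted p between 8.67e-16 and 1.01e-07). Their adjusted p lay between 0.392 and 0.524 with an estimated correlation. Ribosomal protein genes have many near-identical processed copies in the mouse genome, so their values depend on how the authors assigned shared reads.

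By limma, 6236 of the 12884 genes passed the threshold in dKO SNI against dKO sham, 3069 higher and 3167 lower, or 1025 higher and 842 lower with a change of at least 1 on the log2 scale also needed. Without dKO SNI 2 the count was 3887. Bdnf lost its call without dKO sham 2 (adjusted p 0.109), without dKO SNI 1 (0.0509) and without dKO SNI 2 (0.0898).

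**Figure D3:**
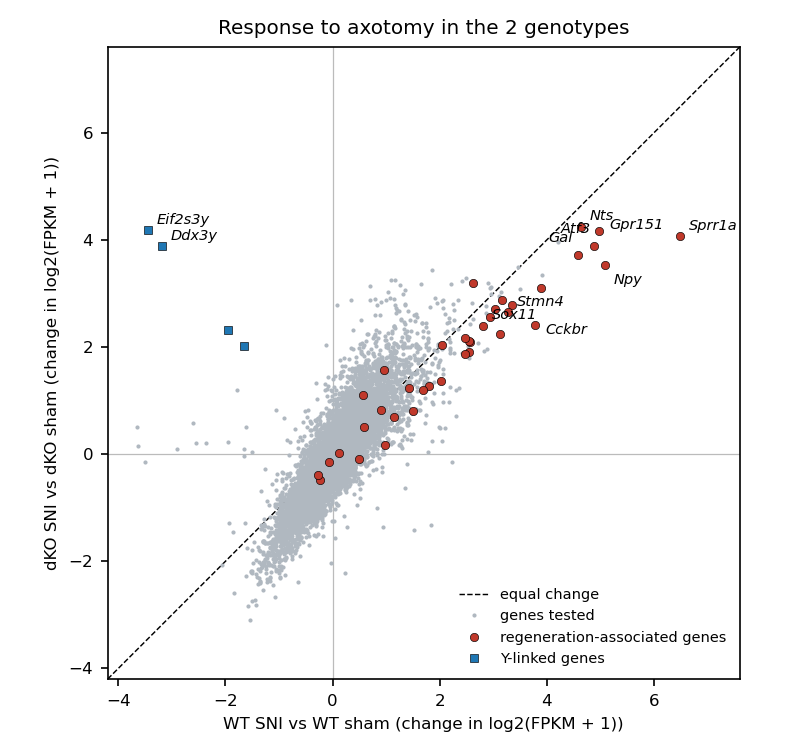
Change in log2(FPKM + 1) with axotomy in dKO mice (vertical axis) against WT mice (horizontal axis) for the 12884 tested genes; red circles are the 38 regeneration-associated genes, blue squares the 4 Y-linked genes, and the dashed line marks equal change. Sprr1a lies at 6.49 and 4.07 and Cckbr at 3.77 and 2.40, below the line, while Eif2s3y and Ddx3y fall in WT and rise in dKO.

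The 2 responses to axotomy, which share no library, were then set against each other. Across the 12884 genes the changes correlated at a Pearson r of 0.825 and a Spearman rho of 0.843, and at 0.953 and 0.961 over the 38 regeneration-associated genes. These are correlations across genes, which are not independent replicates. Among those 38 genes the dKO change grew by 0.77 per unit of WT change, and over all genes by 1.13. Of the 1758 genes called higher in WT, 1428 were called higher in dKO, where independent lists would share 418.8. Of the 1209 called lower 1132 were called lower (297.2 for independent lists), while 12 genes were called in opposite directions, 6 each way. Without WT SNI 2 the correlation over all genes was 0.743.

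Without nerve injury, few single genes passed the test between the genotypes, while 22 of the 31 lists passed camera, 16 higher and 6 lower in dKO sham (adjusted p 0.371 to 0.464 with an estimated correlation). Myh9 was lower in dKO sham than in WT sham (-1.28 ± 0.13) and so was Avil (-1.17 ± 0.17), while Myh10 (-0.60 ± 0.18) did not pass the threshold. Genes of the extracellular matrix were higher in dKO sham: Col3a1 measured 49.4 ± 9.04 against 12.5 ± 1.38 FPKM, the elastin gene Eln 4.61 ± 1.45 against 0.65 ± 0.16 FPKM and the microfibril gene Mfap4 9.50 ± 2.60 against 1.01 ± 0.58 FPKM. Col1a1 (1.79 ± 0.22), the collagen crosslinking enzyme Lox (1.07 ± 0.14) and Col5a2 (1.03 ± 0.14) were higher as well. For Eln and Mfap4 WT sham was the lowest group. WT SNI measured 5.79 ± 0.28 and 8.49 ± 3.45 FPKM, and dKO SNI 5.52 ± 0.04 and 8.33 ± 0.27 FPKM. After injury their genotype changes of -0.06 and 0.03 did not pass the threshold (limma, adjusted p 0.83 and 0.95). Of the 24 fibroblast and matrix genes 6 were higher and 0 lower in dKO SNI than in WT SNI. Tyrp1, a melanocyte enzyme, was higher in dKO sham than in WT sham (2.36 ± 0.13). So were the ubiquitin carrier Ube2c (1.56 ± 0.16), the retinoic acid enzyme Aldh1a2 (1.50 ± 0.21) and the immediate early gene Egr3 (1.24 ± 0.18). Cyp4f39 (-1.22 ± 0.13), Hal (-1.06 ± 0.15) and the 4 Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were lower. Of 24 fibroblast and matrix genes 2 were higher over all genes tested and 14 adjusted over the list alone. Of 34 cell cycle genes the counts were 1 and 18, with Prc1 at 0.84 ± 0.15 and Mcm6 at 0.72 ± 0.14. None of the regeneration-associated genes differed over all genes tested, and 3 were higher adjusted over the list alone, with Stmn4 at 0.71 ± 0.13. Camera gave adjusted p of 8.78e-16, 1.46e-14 and 6.21e-04 for the matrix, cell cycle and regeneration-associated lists, and 0.371 for each with an estimated correlation. Without WT sham 1 the regeneration-associated list was no longer called (adjusted p 0.112). Markers of other cell types moved with the matrix genes by camera, each at an adjusted p of 7.52e-06 and at 0.371 with an estimated correlation. They were the erythrocyte (median 1.19), macrophage (0.42) and myelinating Schwann cell markers (0.39), of which none was called over all genes tested and 2, 4 and 2 were higher adjusted over the list alone. Without dKO sham 2 these medians were 0.63, 0.15 and 0.13, without dKO sham 1 the first and last were 1.95 and 0.72, and without WT sham 2 the last was 0.24. The Schwann cell list lost its call without dKO sham 2 (0.0527). Satellite glia (camera adjusted p 7.68e-04), smooth muscle and pericyte (0.00184), B and plasma cell (0.00424), adipocyte (0.00556) and endothelial markers (0.0116) were higher as lists too, at 0.371 each with an estimated correlation. Of these 1, 1, 5, 3 and 0 genes were higher adjusted over the list alone and none over all genes. Ribosomal protein genes were higher as a list (1.21e-06, and 0.464 with an estimated correlation) with no member called either way. Without dKO sham 2 the ribosomal (0.0794), adipocyte (0.0748) and endothelial (0.162) lists lost their calls, and without WT sham 1 the last 2 did (0.135 and 0.128). The adipocyte list stood at 0.48 with a mean of at least 5 FPKM. The ion channels and receptors (median -0.17) and synaptic vesicle genes (-0.15) were lower as lists (5.02e-06 and 9.07e-05, or 0.371 and 0.423 with an estimated correlation), with no member called either way. Without WT sham 2 the first of these medians was -0.09. The complement and antigen presentation (8.95e-05), stress response (4.36e-04), cytokine and chemokine (0.00171) and immediate early genes (0.00202) were higher as lists, at 0.371 to 0.372 with an estimated correlation. The subtype markers (1.32e-04), cholesterol biosynthesis genes (2.02e-04) and pan-neuronal markers (0.00487) were lower, at 0.371 to 0.454 with an estimated correlation. Of these 7 lists Egr3 and Avil alone were called over all genes tested. Adjusted over the list alone 7 complement genes, 5 immediate early genes and 1 subtype marker were higher and 1 immediate early gene and Avil lower. The cytokine call was lost without dKO sham 2 (0.152), and that of the immediate early genes without the filter on low values (0.174) and with a mean of at least 5 FPKM (0.17). The 10 skeletal muscle markers were lower as a list (median -3.08), with none called over all genes tested and 7 lower adjusted over the list alone. Their camera adjusted p was 1.03e-08, and 0.371 with an estimated correlation, and Ckm stood at 3.17 and 138 FPKM in the 2 WT sham libraries. Without WT sham 2 the median was -0.84.

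In all, 20 genes passed the threshold by limma, 12 higher and 8 lower in dKO sham, and 1397 had an unadjusted p under 0.05. The count was 11 without dKO sham 2. Without WT sham 1 it was 31 and the balance turned, with 9 higher and 22 lower, while a pseudocount of 0.1 gave 55 genes, 47 higher and 8 lower. Tyrp1, Eln, Col3a1 and the Y-linked genes kept their calls without each library in turn. Myh9 (adjusted p 0.00435) stood at 0.051 without WT sham 2, Avil (0.038) at 0.111 to 0.254 without any 1 of the 4 libraries compared, and Mfap4, Col1a1, Ube2c, Aldh1a2, Egr3, Lox, Col5a2, Cyp4f39 and Hal each lost their call without dKO sham 2 (adjusted p 0.0675 to 0.296). All of these but Mfap4 and Ube2c also lost it without WT sham 1 or WT sham 2 (0.0505 to 0.254), and Aldh1a2, Egr3, Col5a2 and Hal without dKO sham 1 (0.0943 to 0.111). Egr3, Col5a2 and Hal stood at 0.0582 without either dKO SNI library, which enter through the shared spread. Without the filter on low values 6 genes passed, 1 higher and 5 lower, and Eln, Col3a1, Mfap4, Col1a1, Lox, Col5a2, Ube2c, Aldh1a2, Egr3, Cyp4f39, Avil and Hal lost their calls (0.0504 to 0.206).

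The comparison of the genotypes after nerve injury asked how injured ganglia of dKO and WT mice differ, and many genes did. Neuronal genes were lower in dKO SNI than in WT SNI. Somatostatin (Sst) measured 5.64 ± 1.63 against 25.1 ± 1.09 FPKM, Mrgprd 3.12 ± 1.74 against 13.6 ± 0.03 FPKM, Rph3a 7.62 ± 1.89 against 24.3 ± 6.42 FPKM and the heavy neurofilament Nefh 97.4 ± 37.8 against 279 ± 113 FPKM. Avil (-1.67 ± 0.17), Cdk5r2 (-1.57 ± 0.24), Sv2c (-1.63 ± 0.33), Parm1 (-1.70 ± 0.29), Lgi3 (-1.56 ± 0.30) and Ugt1a6b (-1.87 ± 0.40), a member of a cluster whose transcripts share exons, were also among the 10 largest falls. Avil, whose promoter drives Cre, was already lower without injury (mean 77.6 FPKM in dKO sham against 176 FPKM in WT sham), and it belongs to the pan-neuronal markers counted below. Myh10 was lower (-1.19 ± 0.18), while Myh9 (-0.29 ± 0.13) did not pass the threshold. Of the 27 synaptic vesicle genes 20 were lower and none higher (24 lower adjusted over the list alone, median -1.0), with Cplx2 at -1.26 ± 0.20 and Syt1 at -1.03 ± 0.18. The counts lower were 27 of 41 for ion channels and receptors (32 adjusted over the list alone), 14 of 30 for subtype markers (19), 11 of 20 for pan-neuronal markers (14) and 17 of 35 for genes of the neuronal cytoskeleton and axon growth (24), with Scn1a at -0.91 ± 0.14, Lpar5 at -0.87 ± 0.13, the transcription factor Pou4f1 at -0.83 ± 0.15 and Dpysl3 at -0.95 ± 0.14. Of the subtype markers 1 was higher, the natriuretic peptide Nppb (1.01 ± 0.24), and of the cytoskeleton genes 1, the mitotic kinesin Kif22 (0.96 ± 0.23), the same adjusted over the list alone. Both lost their calls without the filter on low values (adjusted p 0.058 and 0.0581), without WT SNI 1 (0.101 and 0.138) and without dKO SNI 2 (0.133 and 0.127), and Nppb without WT SNI 2 (0.0546). Camera gave these 5 lists adjusted p between 4.78e-11 and 2.72e-06, and 0.397 with an estimated correlation.

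Genes of myeloid cells and of the interferon response were higher in dKO SNI. All 15 neutrophil markers were higher, also adjusted over the list alone (median 1.71). Mpo measured 59.9 ± 5.09 against 16.8 ± 3.85 FPKM, Elane 82.7 ± 6.15 against 24.5 ± 3.82 FPKM and the antimicrobial peptide Camp 389 ± 15.8 against 100 ± 36.3 FPKM. Among the 10 largest rises were the granule protease Prtn3 (2.26 ± 0.20) and the interferon-induced Slfn4 (2.70 ± 0.46), Isg15 (2.51 ± 0.62) and Ifi27l2a (2.34 ± 0.63). They also held the cytotoxic granule gene Nkg7 (2.35 ± 0.34), BC100530 (2.66 ± 0.43), which belongs to a cluster of near-identical stefin genes, and the ribosomal protein gene Rpl34 (2.74 ± 0.78), beside the Y-linked Eif2s3y, Ddx3y and Uty. Without dKO SNI 2 the change of Ifi27l2a was 1.19. Rpl34 lost its call without each of the 4 compared libraries (adjusted p 0.0846 to 0.146) and with library quality weights (0.0678). Rpl34, Isg15 and Ifi27l2a lost theirs without the filter on low values (0.0704 to 0.0977) and with robust moderation (0.0944 to 0.146), and Ifi27l2a also without WT SNI 2 (0.078). Of 26 macrophage markers 17 were higher (20 adjusted over the list alone, median 1.02), with the myeloid transcription factor Spi1 at 1.48 ± 0.18 and the monocyte receptor Ccr2 at 1.21 ± 0.19. Of 32 interferon response genes 17 were higher (25 adjusted over the list alone), with Psmb9 at 1.48 ± 0.22. Of 23 cytokines and chemokines 11 were higher (14 adjusted over the list alone), with Ccl2 at 1.48 ± 0.21, and of 22 complement and antigen presentation genes 11 (17), with C3 at 1.35 ± 0.23. Of 34 cell cycle genes 30 were higher (32), with Plk1 at 1.14 ± 0.16, and of 52 ribosomal protein genes 42 (50), with Rps19 at 1.18 ± 0.23. These 7 lists passed camera (adjusted p between 2.87e-17 and 2.53e-06), with adjusted p between 0.397 and 0.422 with an estimated correlation. Markers of other cell types moved with them. Of 24 fibroblast and matrix genes 6 were higher (median 0.43), with Igfbp6 at 1.33 ± 0.24 and Dpep1 at 1.13 ± 0.21, of 19 endothelial markers 3 (median 0.35), with Plvap at 0.86 ± 0.22, and of 5 T and NK cell markers 2, Nkg7 and the granzyme Gzma (1.80 ± 0.36). The counts were the same adjusted over the list alone. Camera gave adjusted p of 3.34e-05, 9.33e-04 and 0.0248, and 0.488, 0.397 and 0.397 with an estimated correlation. The T and NK call was lost without dKO SNI 2 (0.0554), with a pseudocount of 0.1 (0.0579) and with quantile normalization (0.0509), and Plvap lost its call without the filter on low values (0.063). The fibroblast median was 0.23 without WT SNI 1 and 0.76 without WT SNI 2. None of the 10 erythrocyte markers passed the threshold (median 0.62; camera adjusted p 0.0687; limma, 5217 of all genes at an unadjusted p under 0.05), with 0 also adjusted over the list alone. Hbb-bs, a globin gene with close paralogs, stood at 4547 and 1921 FPKM in dKO SNI and at 1213 and 3143 FPKM in WT SNI.

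The regeneration-associated genes did not stand apart after injury: of 38, 1 was higher (Gch1, 0.76 ± 0.24) and 2 were lower (Cckbr, -0.65 ± 0.17, and Basp1, -0.58 ± 0.15). None passed adjusted over the list alone, and camera gave an adjusted p of 0.167 (median -0.23). Gch1 lost its call without each library except WT SNI 2 and under 7 further alternatives (adjusted p 0.0502 to 0.31), with a change of 0.34 without WT SNI 1. Cckbr lost its call without the filter on low values (0.0591) and Basp1 with the 4 compared libraries alone (0.0671), and both without WT SNI 1 (0.172 and 0.162) and dKO SNI 2 (0.17 and 0.16). Levels of Atf3, Gpr151 and Stmn4 after injury were chosen to be given after their values were seen. Atf3 measured 156 ± 11.1 FPKM in dKO SNI and 162 ± 22.1 FPKM in WT SNI, Gpr151 65.2 ± 3.93 and 70.3 ± 0.89 FPKM, and Stmn4 89.8 ± 8.60 and 85.0 ± 1.59 FPKM. Among the 43 genes of non-muscle myosin II and its actin regulators, 5 were higher and 7 lower (the same adjusted over the list alone), with Flna at 0.69 ± 0.13 and Was, a gene of blood cells, at 0.97 ± 0.19 (camera adjusted p 0.848).

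By limma, 3106 genes passed the threshold in dKO SNI against WT SNI, 1374 higher and 1732 lower. The balance turned to 363 higher and 185 lower with a change of at least 1 on the log2 scale also needed, and was 742 higher and 1616 lower with a mean of at least 5 FPKM. The count rested on 2 libraries: it was 10 without WT SNI 1 (9 higher) and 11 without dKO SNI 2 (9 higher), where 3171 and 3046 genes had an unadjusted p under 0.05. Of 87 genes named by the fixed rule 6 and 7 stayed past the threshold, Mpo, Prtn3 and Avil in each case, and the adjusted p of the others rose to between 0.0589 and 0.31. Without the filter on low values Nefh and Ugt1a6b stood at 0.0517 and 0.0516.

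**Figure D4:**
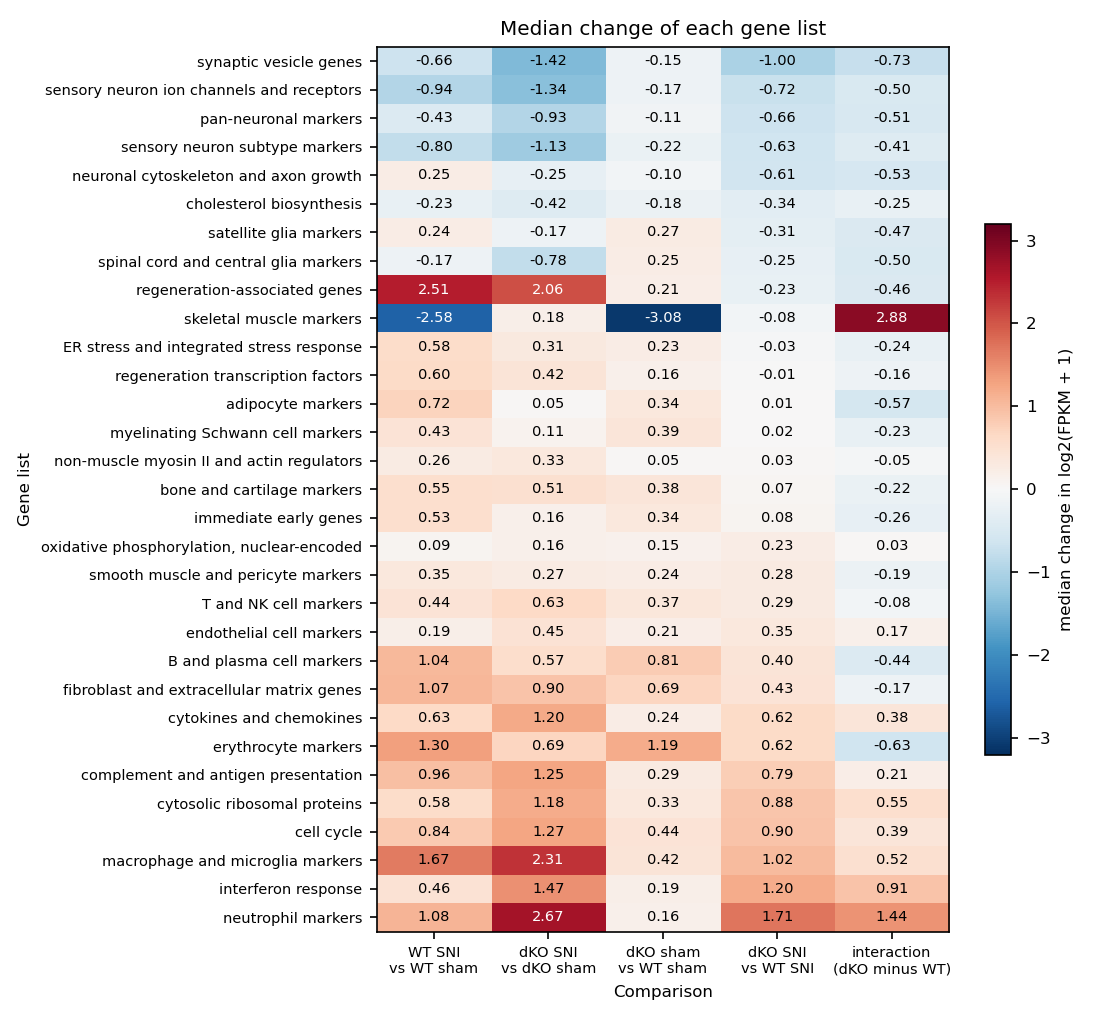
Median change in log2(FPKM + 1) of the tested members of each of 31 gene lists (rows, ordered by dKO SNI vs WT SNI) in 5 comparisons (columns); red is higher and blue lower in the group named first, and for the interaction the dKO response minus the WT response. In dKO SNI against WT SNI the neuronal lists lie at the top (synaptic vesicle genes -1.0) and the neutrophil markers at the bottom (1.71).

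Whether the response to axotomy differed between genotypes was tested gene by gene as the dKO change minus the WT change. The Y-linked genes Eif2s3y (7.63 ± 0.17), Ddx3y (7.06 ± 0.17), Uty (4.27 ± 0.19) and Kdm5d (3.68 ± 0.20) differed most, as this difference sets the libraries with Y-linked transcripts against those without. Tyrp1 rose in WT (3.98 ± 0.53 to 16.8 ± 0.16 FPKM) and fell in dKO (24.6 ± 1.52 to 9.18 ± 0.92 FPKM), a difference of -3.17 ± 0.19. The skin protease gene Asprv1 measured 1.45 ± 0.09 and 2.53 ± 0.24 FPKM in WT sham and WT SNI against 1.22 ± 0.07 and 7.48 ± 0.37 FPKM in dKO sham and dKO SNI (1.40 ± 0.18). The predicted gene Gm38495 also passed (2.55 ± 0.33). Among the neutrophil markers none passed over all genes tested, but 14 of 15 had a larger change in dKO adjusted over the list alone (median 1.44), with S100a8 at 2.16 ± 0.50 and Camp at 1.68 ± 0.38. Of 27 synaptic vesicle genes 15 had a lower change in dKO adjusted over the list alone and none over all genes tested (median -0.73), with Sv2b at -0.97 ± 0.24. None of the regeneration-associated genes passed over all genes, and 1 did, downward, over the list alone (median -0.46; Cckbr -1.37 ± 0.24, Stmn4 -0.63 ± 0.18). Camera called these 3 lists at adjusted p 8.37e-15, 7.08e-08 and 1.18e-04, and each stood at an adjusted p of 0.436 with an estimated correlation. Without dKO SNI 2 the synaptic vesicle median was -0.48.

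For this interaction 7 genes passed the threshold by limma, 6 higher and 1 lower, and 1863 had an unadjusted p under 0.05. On simulated data with independent noise the test recovered 22.8% of genes changed by 1 and 86.1% of those changed by 2 on the log2 scale, with 7 false calls. Without the X- and Y-linked genes only Tyrp1 was called. Tyrp1 also sorted by the Y-linked transcripts. It measured 3.61 to 9.83 FPKM in the libraries of WT sham and dKO SNI, which hold them, and 16.7 to 25.6 FPKM in WT SNI and dKO sham. An effect of sex on Tyrp1 therefore cannot be told apart from a genotype difference in its response. Asprv1 lost its call without each of the 8 libraries in turn (adjusted p 0.0562 to 0.207), Gm38495 without each library except WT SNI 2 and dKO SNI 1 (0.0502 to 0.174), and both under either smaller pseudocount (0.0599 to 0.268) and without the filter on low values (0.234 and 0.263). The count was 20 without WT sham 1, 15 without dKO SNI 1 and 11 without WT SNI 2.

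Which genes differed with genotype over sham and injured ganglia together was read from all 8 libraries with surgery as a covariate. Each genotype then held 1 group with and 1 group without Y-linked transcripts. A term for the presence of those transcripts equals the interaction of genotype and surgery in this design. Adding it therefore cannot set sex apart from that interaction. Avil (-1.42 ± 0.14), Myh10 (-0.90 ± 0.16) and Myh9 (-0.79 ± 0.18) were lower in dKO, with the nociceptor genes Mrgprd (-1.28 ± 0.27), Lpar3 (-0.98 ± 0.22) and Acpp (-0.98 ± 0.21), the vesicle protein Sv2c (-1.16 ± 0.28), Rasgrp1 (-0.95 ± 0.20) and the microtubule protein Map1b (-1.0 ± 0.23). The granule gene Prtn3 (1.50 ± 0.28), the cathepsin Ctse (1.44 ± 0.32), the monocyte gene Ly6c2 (1.51 ± 0.29), Stfa2l1 (1.70 ± 0.25), Ube2c (1.41 ± 0.12) and the complement factor Cfd (1.38 ± 0.37) were higher, as were Rpl34 (2.32 ± 0.56) and the major histocompatibility genes H2-T22 (1.40 ± 0.33) and H2-T23 (1.77 ± 0.40), which have near-identical relatives. In this model 1122 genes passed by limma, 671 higher and 451 lower. The share of higher genes was 59.8%, and 45.1% after median centring, and with a mean of at least 5 FPKM 526 were higher and 586 lower. The count was 4 without dKO sham 2, 9 without dKO SNI 1, 19 without WT SNI 1, 36 without WT SNI 2, 65 without WT sham 2, 74 without dKO SNI 2, 2349 without dKO sham 1, 2866 with a term for the presence of Y-linked transcripts, and 5 without the filter on low values. Avil and Ube2c kept their calls without each library in turn and without the filter. The other genes named here lost theirs without the filter (adjusted p 0.0802 to 0.104) and without dKO sham 2 (0.0784 to 0.0852).

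The injury response averaged over the genotypes, a comparison added after the data were seen, sets 1 group with and 1 group without Y-linked transcripts on each side. The Y-linked Eif2s3y (0.37 ± 0.09) and Ddx3y (0.35 ± 0.09) still passed (adjusted p 0.00541 and 0.00745), though not with a pseudocount of 0.1 (0.0732 and 0.132), so their differences did not cancel fully. Sprr1a (5.28 ± 0.47), Gpr151 (4.58 ± 0.22), Nts (4.44 ± 0.16), Atf3 (4.38 ± 0.21) and Npy (4.30 ± 0.27) rose most, and Htr3a (-2.32 ± 0.16), Mrgprx1 (-2.21 ± 0.24), Nptx1 (-2.21 ± 0.18), Mrgprd (-2.12 ± 0.18) and Rph3a (-2.12 ± 0.16) fell most. Of the 38 regeneration-associated genes 33 rose and 1 fell, and of the 41 ion channels and receptors 34 fell and 2 rose (33 and 1, and 35 and 2, adjusted over the list alone). Camera gave adjusted p of 4.09e-15 and 6.81e-13, and 0.441 for both with an estimated correlation. By limma 7092 of the 12884 genes passed the threshold, 3807 higher and 3285 lower. With a mean of at least 5 FPKM 2019 were higher and 2318 lower, and after quantile normalization 3263 and 3679.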

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

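The 2 counts of library splits were planned. The prediction for sex as the whole cause was written before its result was seen, but it rests on the pattern of the Y-linked genes in these data. All other tests in this part were chosen after the results were seen. Each item below passed the test of the interaction (dKO change minus WT change, log2), by limma for genes and by camera at its preset correlation for lists. The presence of Y-linked transcripts equals this interaction in the design. A genotype difference in the response to axotomy therefore cannot be told apart from the sex of the animals for any of these items.

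Among genes these were Eif2s3y (7.63), Ddx3y (7.06), Uty (4.27), Kdm5d (3.68), Gm38495 (2.55), Asprv1 (1.40) and Tyrp1 (-3.17). Lists with a larger change in dKO had medians of 2.88 (skeletal muscle markers), 1.44 (neutrophil markers), 0.91 (interferon response), 0.55 (cytosolic ribosomal proteins), 0.52 (macrophage and microglia markers), 0.39 (cell cycle), 0.38 (cytokines and chemokines), 0.21 (complement and antigen presentation) and 0.17 (endothelial cell markers). Lists with a lower change in dKO had medians of -0.73 (synaptic vesicle genes), -0.53 (neuronal cytoskeleton and axon growth), -0.51 (pan-neuronal markers), -0.50 (sensory neuron ion channels and receptors), -0.47 (satellite glia markers), -0.46 (regeneration-associated genes), -0.41 (sensory neuron subtype markers) and -0.24 (endoplasmic reticulum and integrated stress responses). The endothelial call was lost without WT sham 2 (adjusted p 0.17), WT SNI 1 (0.16), dKO sham 1 (0.23) or dKO SNI 2 (0.212), that of the stress responses without WT SNI 1 (0.0504) or dKO sham 2 (0.235), and those of the subtype markers (0.0635) and of complement and antigen presentation (0.0676) without dKO SNI 2. With a mean of at least 5 FPKM the calls of the cell cycle (0.137) and stress response lists (0.0608) were lost, and the endothelial call also without the filter on low values (0.0553) and with library quality weights (0.0503). The muscle median rested on WT sham 2, where that list had a median of 5.82 on the log2(FPKM + 1) scale against 1.38 in WT sham 1: it was 0.74 without WT sham 2 and 5.17 without WT sham 1. Other medians moved by over 1.5 times as well. Without dKO SNI 2 they were 0.45 (interferon), 0.23 (cytokines), 0.075 (complement), 0.036 (endothelial), -0.48 (synaptic vesicle) and -0.16 (subtype markers). Without dKO sham 1 they were 0.55 (interferon), 0.34 (ribosomal), 0.27 (macrophage), 0.24 (cell cycle), 0.017 (endothelial) and -0.37 (stress responses). Without WT SNI 1 the ribosomal, cell cycle and endothelial medians were 0.34, 0.19 and -0.0050, the last turned, and without WT sham 1 the ribosomal median was 0.35. The complement median was 0.37 without WT sham 2, 0.33 without WT SNI 2, 0.41 without dKO sham 2 and 0.38 without dKO SNI 1. The endothelial median was 0.097 without WT sham 2, 0.28 without dKO sham 2 and 0.30 without dKO SNI 1, the macrophage median 0.80 without dKO sham 2, and the interferon and cytokine medians 1.52 and 0.58 without dKO SNI 1. None of the lists passed with an estimated correlation (adjusted p 0.436 to 0.494), and 0 passed with fry.

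The Y-linked genes separate WT sham and dKO SNI from WT SNI and dKO sham. All 4 tested Y-linked genes were under 0.1 FPKM in the 4 libraries of the latter groups and above 1 FPKM in the others, as animals of different sex in the groups would give. An exchange of whole groups is argued against by Avil, lower in each dKO library than in each WT library of the same surgery, and by Atf3, whose lowest mean after axotomy was 156 FPKM against at most 9.54 FPKM in sham. Sex as the whole cause of the genotype difference after injury would turn that difference around between sham and injured ganglia, but over the autosomal genes called after injury the 2 differences correlated at r = 0.729. Sex as a part of the 4 comparisons of 2 groups and of the interaction may remain, because the presence of Y-linked transcripts follows the groups. Whether a library holds 1 animal or a pool is not stated, and the X-linked Eif2s3x measured 16.4 FPKM in WT SNI 1, near WT sham (16.5 and 15.5 FPKM), so it does not follow the Y-linked genes in every library.

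Neuronal genes were lower and myeloid genes higher in dKO SNI than in WT SNI. A lower share of neuronal RNA as the whole cause would raise the markers of all other cell types alike, but the macrophage median exceeded the satellite glia median by 1.32 (95% bootstrap interval over members 0.77 to 1.49), with the fibroblast and endothelial medians (0.43 and 0.35) between them. Blood or marrow carried into the ganglia cannot be told apart from infiltrating cells: the erythrocyte median was 0.62 (0.43 to 0.89) beside 1.71 for the neutrophil markers, and Alas2 differed between the dKO SNI libraries (89.8 and 33.1 FPKM). The granule genes Mpo and Elane were alike in those 2 libraries (63.5 and 56.3, and 78.4 and 87.1 FPKM). Both encode granule proteins of myeloid precursors, as do Prtn3 and Ctsg, and Ms4a3 is a further gene of such precursors that does not encode a granule protein. Each of these genes was higher in dKO SNI than in WT SNI (limma, adjusted p 0.0019 to 0.017), and so were 30 of 34 cell cycle genes. The values do not separate mature cells that entered the ganglia from precursors or marrow. The genotype stays open as a hypothesis, as does the sex of the animals as a part, and entry of myeloid cells was not tested.

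Muscle genes were high in WT sham 2 alone. All 10 tested skeletal muscle markers were highest there, as muscle tissue in that library would give, with Tnnc2 at 179 FPKM there and 6.08 FPKM in WT sham 1. No biological explanation was tested, since the design names no group that holds this library alone.

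The rule fixed beforehand counted, among the 35 splits of the 8 libraries into 4 and 4, those with as many genes as the real split. For genotype with surgery as a covariate (1122 genes) 2 of the 35 did, so chance was not excluded by that rule. The other of the 2 is the split by surgery, which follows a structure of the samples. It cannot be fitted beside the covariate and gave 5042 without it, while the highest of the rest was 4. For surgery with genotype as a covariate (6705), only the real split (1 of the 35) reached that count and the highest other gave 5. This is the smallest share the count can give. The rule takes the 8 libraries as independent, which the labels do not state. Splits that mix the surgeries also keep the surgery difference in their residual spread, which lowers their counts. No conclusion on chance is drawn from it.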

How the results depend on the processing

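Leaving out the X- and Y-linked genes or the muscle list, the term for Y-linked transcripts and the injury response averaged over genotypes were chosen after the data were seen, and the other alternatives were planned. No gene named by the fixed rule and past the threshold turned its direction in any of the comparisons under any alternative. In dKO SNI vs WT SNI 1576 of 1802 values of such genes stayed past the threshold, against 998 of 1526 for genotype with surgery as a covariate. With 2 libraries per group, leaving out 1 leaves a lone library that is assumed to vary like the other groups. Unknown read totals limit what can be said of low genes. Except where an alternative tests fewer genes, uses fewer libraries or demands a larger change, the cause was not tested.

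With a mean of at least 5 FPKM, 1869 genes passed in WT SNI vs WT sham, 3880 in dKO SNI vs dKO sham, 3 in the interaction and 4337 in the averaged injury response. With a change of at least 1 on the log2 scale also needed, the counts were 725, 1867, 548 (dKO SNI vs WT SNI), 70 (genotype with surgery as a covariate) and 1208 (averaged). Without the filter on low values, 6 genes passed in dKO sham vs WT sham, 1892 in dKO SNI vs WT SNI and 5 for genotype with surgery as a covariate. In dKO sham vs WT sham 55 genes passed with a pseudocount of 0.1, 32 with only the 4 libraries compared and 34 with library quality weights, which gave 2925 for genotype with surgery as a covariate. A term for Y-linked transcripts, which equals the interaction of genotype and surgery, gave 2866 there. Leaving out X- and Y-linked genes gave 1 in the interaction.

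The replicate numbers only number the libraries: same-numbered deviations correlated at -0.188 to 0.254 between groups. With the replicate number as a replicate block 47 genes passed in dKO sham vs WT sham and 12 in the interaction, and the other counts stayed within 1.5 times.

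Leaving out each library in turn gave 1101 to 3026 genes in WT SNI vs WT sham, 3887 to 6200 in dKO SNI vs dKO sham, 11 to 31 in dKO sham vs WT sham, 10 to 3083 in dKO SNI vs WT SNI, 5 to 20 in the interaction and 4 to 2349 for genotype with surgery as a covariate. The correlation of the injury responses ran from 0.743 to 0.848. With an estimated correlation camera called 0 lists in each of the 5 comparisons. Fry called 13 lists in WT SNI vs WT sham, 21 in dKO SNI vs dKO sham and 15 in dKO SNI vs WT SNI. Of these 11, 17 and 14 also passed camera at its preset correlation. In dKO sham vs WT sham and in the interaction fry called 0, where limma gave 1397 and 1863 genes at an unadjusted p under 0.05. Myh9 in WT SNI vs WT sham, not past the threshold, changed by -0.0136 with median-centred libraries and by -0.0598 to 0.149 with a library left out. Whole reads could not be recovered, and robust moderation was not run for lists, as camera does not use it.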

Other observations

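The test in the last paragraph was chosen after the result was seen, and the lists and their tests were planned. The gene groups given here were fixed before the data were examined. Of 16 immediate early genes 9 rose and 2 fell in WT SNI (10 and 2 adjusted over the list alone), with a camera adjusted p of 0.011, and 0.465 with an estimated correlation; the call was lost without WT SNI 1 (0.0775), without the filter on low values (0.109) and with a mean of at least 5 FPKM (0.142). In dKO SNI against dKO sham 4 immediate early genes rose and 1 fell, the same adjusted over the list alone (camera adjusted p 0.265). Of 24 genes of cholesterol biosynthesis 13 fell and 2 rose in dKO SNI against dKO sham, the same adjusted over the list alone (camera adjusted p 0.00689, and 0.537 with an estimated correlation). In WT SNI 4 fell and 2 rose, the same adjusted over the list alone (camera adjusted p 0.0064, and 0.559 with an estimated correlation). The difference between the responses did not pass camera (adjusted p 0.13). In dKO SNI 9 were lower than in WT SNI (11 adjusted over the list alone, camera adjusted p 9.45e-04, and 0.488 with an estimated correlation). Of 34 nuclear-encoded genes of oxidative phosphorylation 0 passed in WT SNI by limma, against 6 higher and 6 lower in dKO SNI, the same adjusted over the list alone, and neither list test passed (camera adjusted p 0.955 and 0.689).

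Of 20 satellite glia markers 4 rose and 0 fell in WT SNI (camera adjusted p 0.0704), while 4 rose and 6 fell in dKO SNI (0.29), the same adjusted over the list alone. The 22 myelinating Schwann cell markers had medians of 0.43 and 0.11, with a camera adjusted p of 0.00536 in WT, or 0.563 with an estimated correlation, lost without WT sham 2 (0.0668) and WT SNI 1 (0.0769). The 19 endothelial markers had medians of 0.19 and 0.45 (camera adjusted p 0.13 and 0.0178, the latter 0.524 with an estimated correlation and lost without dKO sham 1, 0.0804). Erythrocyte markers had medians of 1.3 and 0.69 (0.00536 and 0.16, the former 0.563 with an estimated correlation and lost without WT SNI 2, 0.0618, where the median was 0.60; it was 2.00 without WT SNI 1). Camera adjusted p in WT and dKO was 0.21 and 0.595 for smooth muscle and pericyte markers, 0.337 and 0.16 for T and NK cell markers, 0.061 and 0.265 for B and plasma cell markers, 0.295 and 0.921 for adipocyte markers, 0.538 and 0.408 for spinal cord and central glia markers and 0.451 and 0.61 for bone and cartilage markers. The median and mean of the oxidative phosphorylation list in WT (0.09 and 0.07) and of the adipocyte list in dKO (0.05 and 0.06) were above 0 where the test pointed down.

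The regeneration-associated list had an interaction median of -0.46 (camera adjusted p 1.18e-04, and 0.436 with an estimated correlation), with none of its 38 genes past the threshold over all genes tested. Pan-neuronal markers stood at -0.51, and the 2 medians differed by 0.0437 (95% bootstrap interval over members -0.16 to 0.26), as a smaller neuronal share of the RNA after injury in dKO would give. In dKO SNI against WT SNI, where such a share would also lower both lists alike, the medians of -0.23 and -0.66 differed by 0.434 (0.20 to 0.70). A difference of 0.323 (0.24 to 0.49) was already there in sham ganglia, so that comparison holds more than the injury. The medians in dKO sham against WT sham were 0.21 for the regeneration-associated genes and -0.11 for the pan-neuronal markers. Part of the interaction median of -0.46 therefore lies in the sham ganglia, and a smaller neuronal share after injury would not give that part. As a part of the pattern a smaller neuronal share stays open as a hypothesis, as does the sex of the animals, which is aliased with this interaction.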
